A study of Mus musculus with 4 samples.

How the data were processed

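Poly-A-enriched RNA of male and female CD-1 mouse liver was sequenced with a strand-specific preparation, per the labels' protocols. The series' design text gives 12 livers per sex, combined into 2 pools of 6 livers for each sex, which makes 4 pooled libraries. Bowtie and edgeR are named as the authors' tools and mm9 as the genome build in the submitters' processing notes, without versions or roles. How reads were assigned to genes and whether the counting used strand is not given in the sources used here.

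A single table of 21827 gene entries was used. Per the file headers, it holds the authors' log2 RPKM per sex, the authors' normalized log2 ratio of male over female liver, their linear ratio, their signed fold change as a score with a minus sign where female liver was higher, their adjusted p-value for the sex difference, a flag for liver-expressed genes (log2 RPKM of at least 1 in either sex) and a class at an adjusted p under 0.01. The method of the adjustment is not given in the sources used here. The 2 pools of a sex are not separated, so the spread between pools cannot be computed, no gene was tested anew and no pool was left out. The planned test on counts per library could therefore not be run, and the fallback fixed with it was used: a gene was called at the authors' adjusted p under 0.05, with the direction of their normalized ratio. The adjustment cannot be restricted to a list, since unadjusted p-values are not given, so no count adjusted over the list alone can be stated.

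Genes were sorted by what the values show. Genes with a ratio of 1 whose levels in both sexes differ by 0.389 on the log2 scale lie at the floor of the scale (6590 genes); 14 more have no level. All 6604 carry an adjusted p of 0.026, which was disregarded. Genes with a ratio of 1 that lie at the floor in 1 sex and at a whole multiple of it (within 0.3%) in the other numbered 1460; 80 of these have an adjusted p under 0.05, and none was called, because no ratio is given. The other 13763 genes were compared, 5 of them without a level.

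Depth was recovered from the floor, taking the value added by the authors as 1 read and the spans of olfactory receptor genes at the floor, which gives 11241814 reads for male and 14718990 for female liver. The sum over genes with a known transcript length came to 8.42 M and 11.2 M. Lengths were taken by RefSeq accession from GENCODE vM21, which is on another build and served for names and lengths alone. Of 4668 floor genes with such a length, 3454 (74.0%) had an implied length within 2% of it. Implied reads are therefore approximate and are given for genes with a matching length. Where they are used, a 95% exact (Clopper-Pearson) interval of the ratio of reads is given. It covers counting error alone, not differences between mice or pools. Reads are scaled in it by implied depth and not by the authors' normalization, so an authors' fold can lie outside it. For 121 genes at an adjusted p under 0.01 and an authors' log2 ratio beyond 1 in either direction, the normalized ratio equals the plain difference of levels within 0.0015 on the log2 scale, and of the 87 with a length 77 had under 0.5 implied reads in the lower sex, against 0 of 520 other such genes. These were taken as having no reads in the lower sex, and their fold is given as a bound (at least) against a floor of 3 reads over the sex. This bound leaves out counting error in the higher sex, so the exact interval can start lower.

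Gene lists, 55 in number, were written before the data were examined from general knowledge of mouse liver. Of their members, 10 were matched through older symbols in a RefSeq gene table and 42 were not found. For the 51 lists with at least 5 compared members, the median log2 ratio was set against the medians of 10000 random lists of the same size, drawn with replacement within 10 bins of mean level; this describes these libraries and is not a test over mice. Chromosomes were compared with two-sided Fisher's exact tests and neighbours with 10000 random placements of the calls. Named genes followed a rule fixed before the data were examined: the 10 largest ratios in each direction among called genes with a level above the median (log2 RPKM 2.57), leaving out identifier-only symbols, Y-linked genes and Xist; up to 4 called members per list by size of ratio, or up to 2 of the highest level where fewer than 2 were called; up to 8 for growth hormone signalling and for transcription factors; the Y-linked genes and Xist; and the members of the 5 longest runs, the fifth being 1 of 3 with 6 genes. Not every gene chosen by this rule is given here. Where few called members of a list fell outside this rule, they are named without values, chosen after their values were seen. Coordinates are those of the table (mm9), converted to a 1-based start.

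The statistics were tested on simulated data made by shuffling the ratios or calls of 13758 genes. Lists of 15 genes shifted by 1 on the log2 scale fell outside the central 95% in 100 of 100 repeats, and unshifted lists in 4 of 100. Planted runs of 5 neighbours were found in 20 of 20 repeats and unplanted ones in 0 of 20, and 43 extra calls on the X in 100 of 100 repeats, against 4 of 100 without them. The planted list shifts and X calls are larger than many differences reported here, so the power for smaller ones is not known. Shuffling also removes any relation between genes, so the rates without a planted effect hold for unrelated genes alone. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 was used, with random seed 1. Alternatives were other thresholds of adjusted p and fold, a minimum level, random lists not matched on level, lists by symbol alone, neighbours within 100 kb, and, added after the data were seen, the plain difference of log2 RPKM values, members or genes with a log2 RPKM of at least 1, and neighbours without shared symbol stems.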

Results

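Liver RNA from untreated CD-1 mice, an outbred stock, was compared between males and females at 8 weeks of age. RNA from 12 livers per sex had been combined into 2 pools of 6 livers, and each of the 4 pools was sequenced as poly-A-enriched, strand-specific RNA. The table used here gives 1 value per gene and sex and none per pool, so error between pools could not be computed here. Levels, folds and adjusted p-values of single genes are the authors' own, except bounds against a floor of 3 reads and counting intervals. Each bound (at least) leaves out counting error in the higher sex, so the counting interval can start lower. The comparison addresses which genes differ in expression between male and female liver. Of 21827 gene entries, 6590 lay at the floor of the scale in both sexes, 14 more had neither a level nor a ratio other than 1, and 1460 rose above the floor in a single sex with the ratio set to 1. The remaining 13763 genes had a ratio between the sexes and are called the compared genes. Where the added value at the floor is taken as 1 read, the levels imply 11241814 reads for male and 14718990 for female liver, a ratio of 1.31.

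The sex labels were checked with genes of the sex chromosomes. Xist, the RNA that silences an X chromosome in female cells (X, 100658854 to 100678556, mm9), was 720-fold higher in female liver in the authors' deposited table (adjusted p = 7.54e-219). Of 8 Y-linked genes, 4 were compared, and all 4 were higher in male liver. Ddx3y, an RNA helicase gene (Y, 597158 to 623056, mm9), and Kdm5d, a histone demethylase gene, had no implied reads in female liver, and were at least 686-fold and at least 116-fold higher in male liver against a floor of 3 reads. Counting alone allows folds as low as 557 for Ddx3y and 93.8 for Kdm5d. Eif2s3y and Uty were 1130-fold and 1070-fold higher in male liver in the authors' deposited table. Their normalized log2 ratios were 10.14 and 10.06, whereas the plain differences of log2 RPKM values were 9.17 and 9.09. The size of these folds is therefore uncertain, and no counting interval was computed for either gene. Zfy1, Zfy2 and Sry lay at the floor in both sexes, and Usp9y had 1 implied read in female liver and none in male liver. Among 5 genes known to escape X inactivation, Xist, Eif2s3x (2.34-fold, adjusted p = 0.0048) and Kdm6a (1.75-fold, adjusted p = 0.000135) were higher in female liver in the authors' deposited table.

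At an adjusted p under 0.05, 2399 of the 13763 compared genes differed between the sexes in the authors' deposited table, 992 of them higher in male and 1407 higher in female liver. The authors' own classes, at an adjusted p under 0.01, hold 573 male-biased and 833 female-biased genes. The median difference was 1.74-fold for the male-higher and 1.97-fold for the female-higher genes. By the authors' ratio, which is not bounded for genes with no implied reads in 1 sex, differences were at least 2-fold for 392 male-higher and 692 female-higher genes. The called female-higher genes were less abundant, with a median log2 RPKM of 1.91 in the higher sex against 3.04 for male-higher genes. Implied depth was 1.31 times as high in female liver, and its effect on calls at low levels was not tested.

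**Figure D1:**
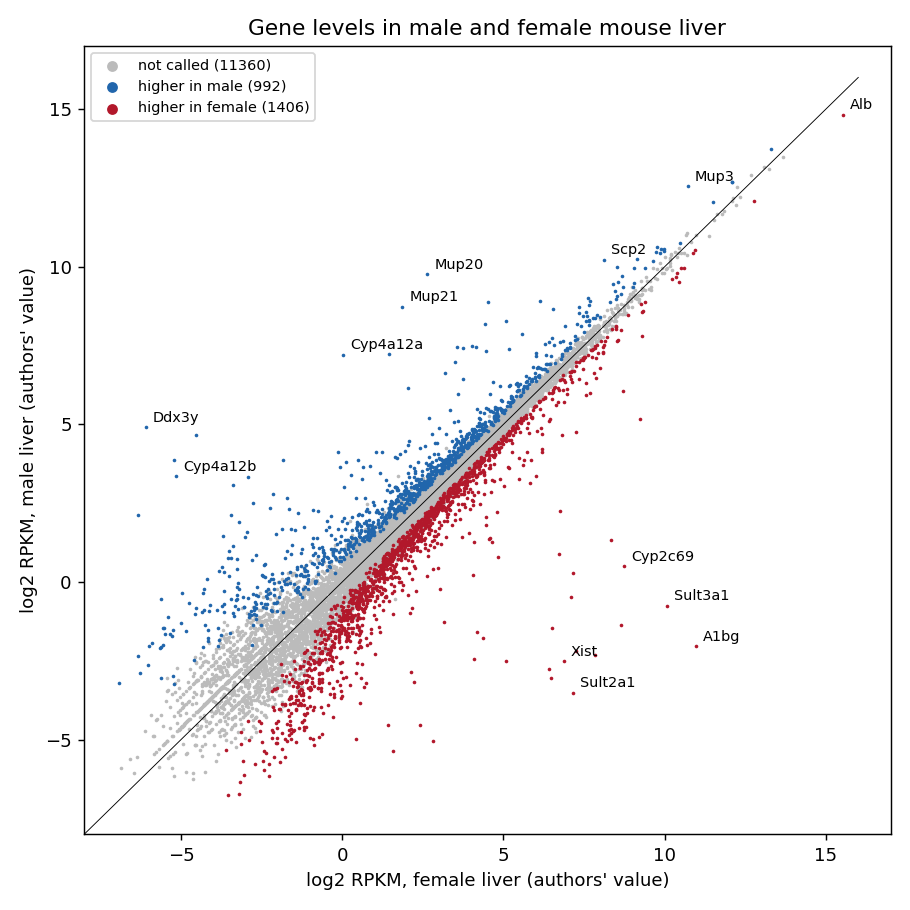
Level of each compared gene in female (x axis) and male liver (y axis), in log2 RPKM as the authors gave it, 1 point per gene, coloured by the call at an adjusted p under 0.05. The 992 male-higher genes lie above the diagonal and 1406 of the 1407 female-higher genes below it, 1 having no level; A1bg, Sult3a1 and Sult2a1 lie farthest below.

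Female-higher genes with large ratios encode a secreted protein and enzymes and transporters of steroid and drug metabolism. A1bg, a plasma glycoprotein gene (15, 60749144 to 60752825, mm9), was 10756-fold higher in female liver in the authors' deposited table (adjusted p = 1.31e-276), with a log2 RPKM of 10.97 in female and -2.04 in male liver. Its male level corresponds to 4 implied reads, so that counting alone allows a difference between 4010-fold and 37700-fold (exact 95% interval). Sult3a1, a sulfotransferase gene, was 2316-fold higher in the authors' deposited table, and Slc22a26, an organic anion transporter gene, 898-fold. The cytochrome P450 genes Cyp2c40, Cyp2c69 and Cyp2a4 were 833-fold, 320-fold and 288-fold higher in female liver in the same authors' deposited table, and Sult2a5 was 397-fold higher. Sult2a1 and Sult2a2, which encode sulfotransferases of hydroxysteroids, had no implied reads in male liver and were at least 538.5-fold and at least 245-fold higher in female liver against the floor of 3 reads. Counting alone allows folds as low as 438 for Sult2a1 and 199 for Sult2a2. The implied reads in male liver were 2 for Cyp2c40 and 1 for Sult2a5, and counting alone allows 239-fold to 7150-fold and 71.5-fold to 15800-fold.

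Among male-higher genes above the median level, Y-linked genes left out, the largest ratios belonged to fatty acid hydroxylases and major urinary proteins. Cyp4a12b (4, 115084229 to 115111639, mm9) had no implied reads in female liver and was at least 120.0-fold higher in male liver (as low as 97-fold by counting). Its neighbour Cyp4a12a was 151-fold higher in the authors' deposited table (adjusted p = 1.01e-144). The major urinary protein genes Mup7, Mup20, Mup21 and Mup9 were 140-fold, 136-fold, 128-fold and 23.1-fold higher in the authors' deposited table. The implied reads in female liver were 1 for Mup7, 84 for Mup20 and 35 for Mup21, and for Mup7 counting alone allows 26.5-fold to 6000-fold. Elovl3, a fatty acid elongase gene, was 57.5-fold higher in male liver in the authors' deposited table, Cml5 67.3-fold and Capn8, a calpain gene, 33.6-fold. Cml5 had 3 implied reads in female liver, and counting alone allows 23.8-fold to 346-fold. Lcn13, a lipocalin gene, had no implied reads in female liver and was at least 28.8-fold higher in male liver (as low as 22.8-fold by counting).

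Lists of genes known to be sex-biased in mouse liver moved as their names say. Of 35 compared members of the male-biased list, 32 were higher in male liver and none in female liver, with a median log2 ratio of 2.91. Of 58 compared members of the female-biased list, 53 were higher in female liver, with a median log2 ratio of -2.76, and Tff3 and Adh4 were higher in male liver. These lists come from general knowledge of mouse liver, part of which can rest on related samples, so they are not independent evidence of direction. Over all 51 gene lists with at least 5 compared members, 11 medians lay above and 19 below the central 95% of the medians of 10000 random lists of the same size and level. For lists of unrelated genes, chance would place 2.55 outside. These lists include the known sex-biased genes, some share members, and members can be related, so the number outside is a description and not a test.

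**Figure D2:**
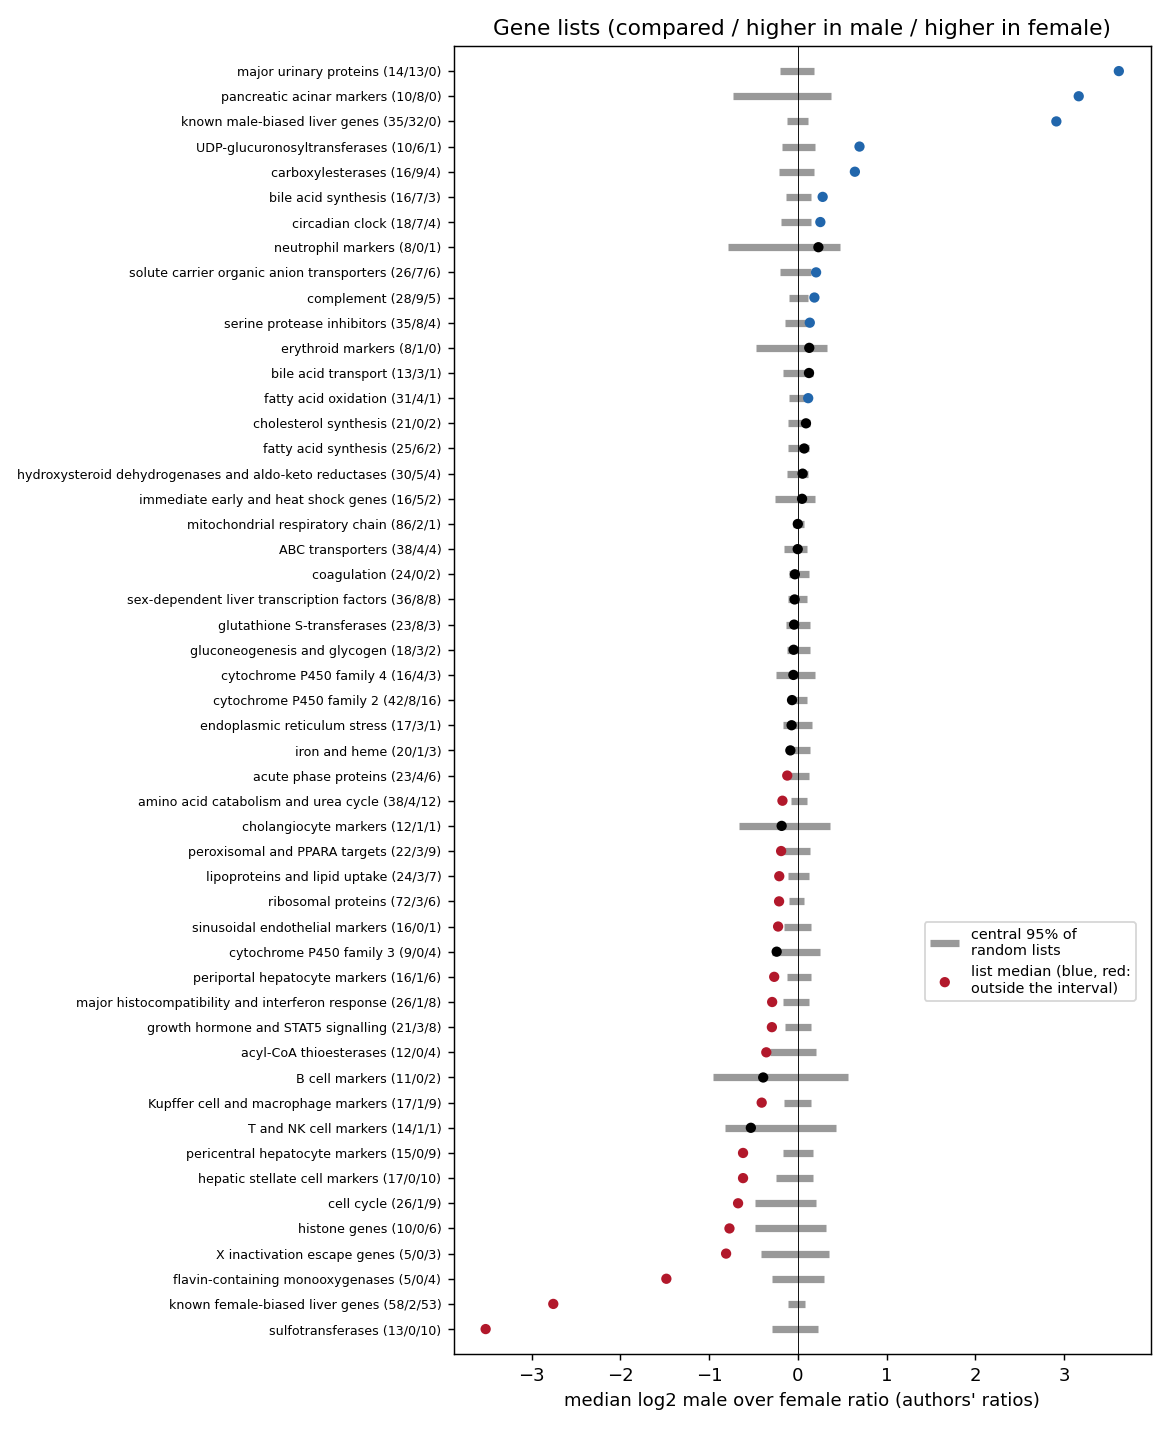
Median log2 male over female ratio of each gene list (points), with the central 95% of the medians of 10000 random lists matched on level (grey bars); numbers after each name give its compared, male-higher and female-higher members. Major urinary proteins have a median of 3.62 and sulfotransferases one of -3.52, or 3.51 and -1.83 with genes that had no implied reads in 1 sex at their bounds.

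Drug and steroid metabolizing enzymes differed between the sexes by family. Of 13 compared sulfotransferase genes, 10 were higher in female liver and none in male liver. Their median log2 ratio was -3.52, below all 10000 random lists, and -1.83 with 4 genes that had no implied male reads set to their bounds. Of the flavin-containing monooxygenases, Fmo2 (5.64-fold), Fmo1 (2.79-fold) and Fmo4 (2.51-fold) were higher in female liver in the authors' deposited table. Family 2 of the cytochromes P450 went both ways, with 16 female-higher and 8 male-higher genes of 42 and a median of -0.07 inside the random range, and at -0.11 outside it over members with a log2 RPKM of at least 1. Cyp2b9 was 146-fold higher in female liver in the authors' deposited table. Among 9 compared family 3 genes, 4 were higher in female liver, Cyp3a44 by 205-fold and Cyp3a16 by 24.9-fold in the authors' deposited table, and Cyp3a41b and Cyp3a41a by at least 40.5-fold and at least 20.1-fold; the median of -0.24 lay inside the random range, and outside it at -0.27 by the plain difference of log2 RPKM values and at -2.44 over members with a log2 RPKM of at least 1. In family 4, Cyp4a14 (3.83-fold) and Cyp4a10 (3.20-fold) were higher in female liver in the authors' deposited table, against the male-higher Cyp4a12 genes, and in all 4 of 16 genes were higher in male and 3 in female liver, with Cyp4a32 and Cyp4f13 male-higher and Cyp4a31 female-higher.

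Glucuronosyltransferases and carboxylesterases lay on the male side. Of 10 compared genes of the glucuronosyltransferase list, 6 were higher in male liver (median log2 ratio 0.69, above all 10000 random lists). Among them were Ugt2b38 (13.8-fold), Ugt2b5 (2.36-fold) and Ugt2b1 (2.19-fold) in the authors' deposited table, and Ugt3a1, of a related family that transfers other sugars. Ugt2b37 was 9.55-fold higher in female liver in the authors' deposited table. Of 16 carboxylesterase genes, 9 were higher in male and 4 in female liver (median 0.64, above all 10000 random lists). Ces4a (4.85-fold) and Ces2c (4.66-fold) were higher in male liver and Ces1a 2.58-fold higher in female liver in the authors' deposited table, and Ces2b was at least 10.9-fold higher in male liver (as low as 8.23-fold by counting). Ces1b, Ces1c and Ces1d were the other female-higher members. Glutathione S-transferases went both ways, 8 male-higher and 3 female-higher of 23, with a median of -0.04 inside the random range: Gstp1 was 11.4-fold and Gsta1 2.88-fold higher in male liver, and Gstt3 4.0-fold and Mgst3 3.14-fold higher in female liver, in the authors' deposited table, and Gstt1 was also female-higher. Many of these genes have near-identical paralogs, and reads split between copies leave the ratio of a single member uncertain.

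**Figure D3:**
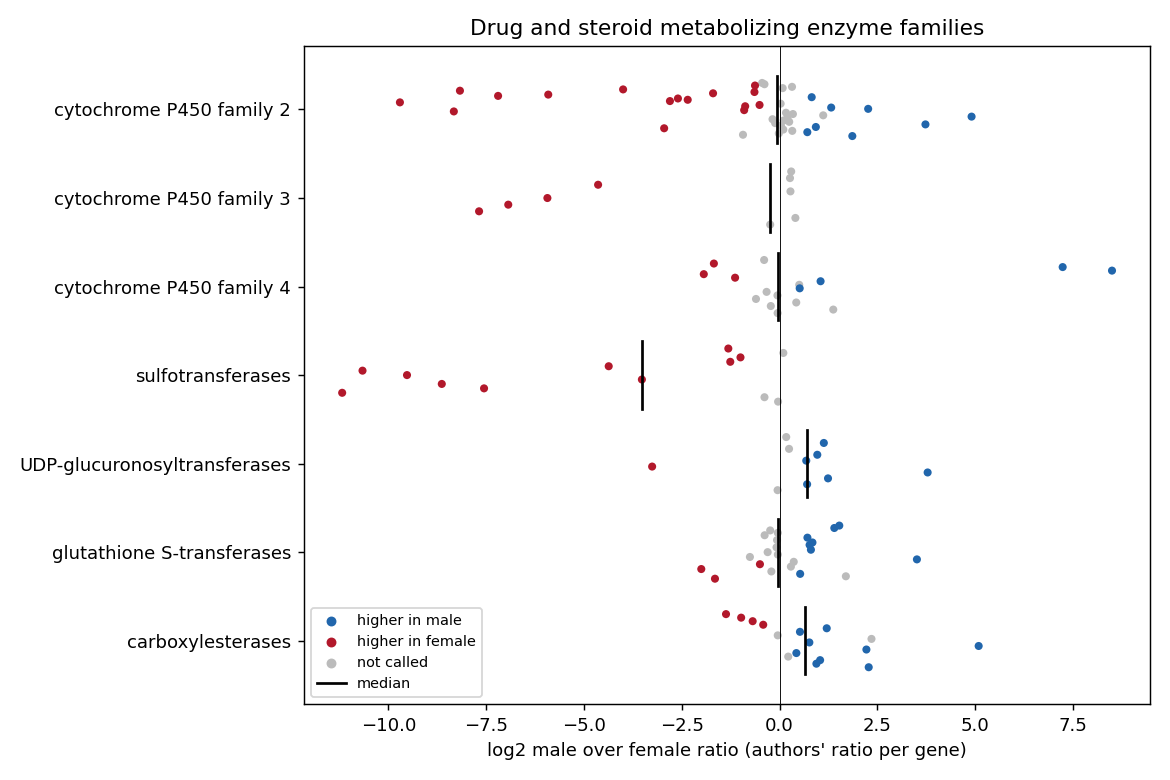
Log2 male over female ratio of each compared gene (1 point per gene, authors' ratio) in 7 enzyme families, with the family median as a black bar and colour for the call at an adjusted p under 0.05. Sulfotransferases hold no male-higher gene, and family 2 of the cytochromes P450 reaches from Cyp2c40 at -9.70 to Cyp2d12 at 4.91. Genes with no implied reads in 1 sex, such as Cyp4a12b, are drawn at the authors' ratio.

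Secreted proteins of the liver differed as well. Of 14 compared major urinary protein genes, carriers of pheromones in urine, 13 were higher in male liver (median log2 ratio 3.62, above all 10000 random lists, and 3.51 with Mup12 at its bound of at least 11.35-fold). Because these genes are near-identical, values of single members are uncertain. Complement genes lay on the male side, with 9 of 28 higher in male and 5 in female liver (median 0.19, at or above 9989 of 10000 random lists). The terminal components C6 (15.01-fold), C9 (2.98-fold) and C8a (2.78-fold), and C4a (5.24-fold), were higher in male liver in the authors' deposited table, and C1qa, C1qb, C1qc, C3 and Mbl2 were female-higher. Serine protease inhibitors had 8 male-higher and 4 female-higher genes of 35 (median 0.13, at or above 9918 random lists, inside their range when the plain difference of log2 RPKM values was used). Serpine2 (8.93-fold), Serpina12 (4.60-fold) and Serpina7, the thyroxine-binding globulin gene (3.47-fold), were higher in male and Serpina3i (3.85-fold) in female liver in the authors' deposited table; Serpina6, Serpinb1a and Serpinb8 were also female-higher. Acute phase genes went both ways, 4 male-higher and 6 female-higher of 23 (median -0.12, at or below which lay 187 of 10000 random lists; inside the range of random lists not matched on level). Hamp2, a hepcidin gene (18.1-fold), and Lcn2 (8.98-fold) were higher in female, and Saa2 (3.45-fold) and Saa1 (3.33-fold) in male liver in the authors' deposited table. For Saa2 and Saa1 the plain differences of log2 RPKM values were 1.375 and 1.276, against normalized log2 ratios of 1.789 and 1.734. The size of these 2 folds is therefore uncertain. Il1r1 and Hpx were also male-higher. Of 24 genes of the coagulation list, Ahsg, a plasma protein gene that encodes no clotting factor (1.60-fold), and F7 (1.39-fold) were higher in female liver in the authors' deposited table. None was higher in male liver, and the median of -0.03 lay inside the random range. Among 20 iron and heme genes, the hepcidin genes Hamp2 and Hamp (1.74-fold) were higher in female and Fech (1.30-fold) in male liver in the authors' deposited table; the median of -0.09 lay inside the random range and outside it by the plain difference of log2 RPKM values.

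Transporters and bile acid genes differed in both directions. Of 26 organic anion and cation transporter genes, 7 were male-higher and 6 female-higher, with Slc22a26 and Slc22a27 (80.9-fold) higher in female and Slc22a19 (13.99-fold, 1 implied read in female liver, 2.09-fold to 620-fold by counting) in male liver in the authors' deposited table, and Slc22a17 at least 3.56-fold higher in female liver. The list median of 0.21 lay at or above 9951 of 10000 random lists, and inside the random range over members with a log2 RPKM of at least 1. ABC transporters had 4 genes called each way of 38 (median inside the random range): Abcd2, which imports fatty acids into peroxisomes (14.6-fold), Abca4 (14.6-fold, 1 implied read in male liver, 2.31-fold to 603-fold by counting) and Abcb1a (4.48-fold) were higher in female and Abcg2 (2.47-fold) in male liver in the authors' deposited table. Abcb1b was also female-higher, and Abcb10, Abcg8 and Abcd3 male-higher. In bile acid synthesis, 7 of 16 genes were male-higher and 3 female-higher (median 0.28, at or above 9997 random lists). Cyp7b1, the oxysterol hydroxylase gene of the alternative pathway (9.67-fold), and Scp2 (4.30-fold) were higher in male liver, and Cyp39a1 (5.38-fold) and Cyp7a1, the rate-limiting enzyme gene of the classical pathway (2.51-fold), in female liver in the authors' deposited table, with Akr1d1 the third female-higher member. Of 13 bile acid transport genes, Slco1a1 (2.18-fold), Abcg8 (1.71-fold) and Atp8b1 (1.32-fold) were higher in male and Slco1a4 (2.96-fold) in female liver in the authors' deposited table; the median of 0.13 lay inside the random range, and at 0.27 outside it over members with a log2 RPKM of at least 1. Hydroxysteroid dehydrogenases and aldo-keto reductases had 5 male-higher and 4 female-higher genes of 30 (median 0.05, inside the random range): Hsd3b5 was 7.53-fold and Hsd3b2 2.53-fold higher in male, and Akr1c18 7.53-fold and Hsd3b1 2.14-fold higher in female liver in the authors' deposited table, with Akr1c19, Akr1c13 and Hsd17b4 also male-higher and Akr1d1 and Akr1c20 female-higher.

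Genes of lipid metabolism differed in both directions. Of 12 acyl-CoA thioesterase genes, 4 were higher in female liver and none in male liver (median -0.36, with 125 of 10000 random lists at or below), Acot3 by 68.4-fold, Acot4 by 3.08-fold, Acot1 by 1.66-fold and Acot13 by 1.44-fold in the authors' deposited table. Peroxisomal genes and targets of PPARA, the fatty acid receptor, had 9 female-higher and 3 male-higher genes of 22 (median -0.19, with 143 random lists at or below; inside the random range without matching on level, and by the plain difference of log2 RPKM values). Among them Acot3, Cyp4a14, Cyp4a10 and Acot4 were female-higher, and Fabp1 and Acaa1b male-higher. Fatty acid oxidation had 4 male-higher genes of 31 (median 0.12, at or above 9805 random lists; inside the range under the same changes), among them Acsl1 (1.41-fold), Ppara (1.39-fold) and Acaa1b (1.31-fold), and Pdk4, an inhibitor of pyruvate dehydrogenase, was 1.69-fold higher in female liver in the authors' deposited table. In fatty acid synthesis, 6 of 25 genes were male-higher and 2 female-higher (median 0.07, inside the random range and outside it by the plain difference). Me1 (1.68-fold), Scd1 (1.54-fold) and Thrsp (1.52-fold) were higher in male and Pnpla3 (1.84-fold) in female liver in the authors' deposited table, with Fads1 the other female-higher gene. Of 21 cholesterol synthesis genes, 2 were called, both higher in female liver, among them Mvd (1.41-fold) in the authors' deposited table, with a median of 0.09 inside the random range. Lipoprotein and lipid uptake genes had 7 female-higher and 3 male-higher members of 24 (median -0.21, with 3 random lists at or below; inside the range without matching on level). Vldlr (2.99-fold), Lipg (1.85-fold) and Apoa4 (1.59-fold) were higher in female and Apoa1 (1.49-fold) in male liver in the authors' deposited table, and Pltp and Apob were also male-higher.

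Amino acid catabolism and the urea cycle lay on the female side, with 12 of 38 genes female-higher and 4 male-higher (median -0.17, below all 10000 random lists). Oat (2.28-fold), Mat1a, which makes S-adenosylmethionine (1.98-fold), Got1 (1.91-fold) and Cth (1.85-fold) were higher in female liver in the authors' deposited table, and Tdo2, Kmo and Kynu of tryptophan breakdown and Sdsl were male-higher. Of 18 genes of gluconeogenesis and glycogen, Gys2, the liver glycogen synthase gene (1.93-fold), and Gbe1 (1.59-fold) were higher in male, and Ppp1r3c (1.76-fold) and Ppp1r3b (1.68-fold), which target a phosphatase to glycogen, in female liver in the authors' deposited table; the median of -0.05 lay inside the random range.

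Growth hormone, whose pattern of secretion differs between the sexes, acts in liver through STAT5. Of 21 genes of this signalling, 8 were female-higher and 3 male-higher (median -0.29, below all 10000 random lists). The prolactin receptor gene Prlr (2.97-fold), the binding protein genes Igfbp3 (2.83-fold) and Igfbp1 (2.34-fold), the feedback inhibitor gene Socs2 (1.75-fold), Igfals (1.64-fold), Irs1 (1.54-fold), Stat5a (1.46-fold) and Ptpn6 (1.42-fold) were higher in female liver in the authors' deposited table, and Ghr, Cish and Igfbp2 were higher in male liver. A list of 36 transcription factors and regulators of sex-dependent liver genes went both ways, 8 called in each direction, with a median of -0.04 inside the random range. Cux2 (36.3-fold), Tox (6.45-fold), Trim24 (3.53-fold), Sall1 (3.44-fold) and the oestrogen receptor gene Esr1 (1.69-fold) were higher in female liver in the authors' deposited table. Ihh, a secreted signal (4.90-fold), Zbtb20 (2.45-fold) and the repressor gene Bcl6 (2.20-fold) were higher in male liver in the authors' deposited table.

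Hepatocytes differ along the axis of the liver lobule, and markers of both ends lay on the female side. None of 15 pericentral markers was male-higher and 9 were female-higher (median -0.62, below all 10000 random lists), with Lgr5 at 2.64-fold, Cyp7a1 at 2.51-fold, Oat at 2.28-fold and the ammonium transporter gene Rhbg at 1.62-fold in the authors' deposited table. Of 16 periportal markers, 6 were female-higher (median -0.27, with 2 random lists at or below; inside the range without matching on level), among them Aldh1b1 (1.99-fold), Ctsc (1.90-fold) and Alb, the albumin gene (1.62-fold, adjusted p = 0.000181), and Cyp2f2 was 1.90-fold higher in male liver in the authors' deposited table.

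Among 26 cell cycle genes, 9 were female-higher (median -0.67, with 18 of 10000 random lists at or below). Ccnd1, the cyclin D1 gene (4.35-fold), and Ccna2 (2.44-fold) were higher in female and Ccne1 (3.38-fold) in male liver in the authors' deposited table. Plk1 rested on 2 and 16 implied reads and was 6.24-fold higher in female liver in the authors' deposited table, with 1.44-fold to 54.8-fold allowed by counting. Histone genes had 6 female-higher members of 10 (median -0.77, with 13 random lists at or below), Hist1h1d by 4.92-fold, Hist2h2bb by 3.61-fold and Hist1h1c by 1.79-fold in the authors' deposited table. Hist1h2ac was at least 2.29-fold higher in female liver against the floor of 3 reads, and counting alone allows a fold as low as 1.51. Many replication-dependent histone transcripts lack a poly-A tail, so that poly-A enrichment captures them in part. Genes of antigen presentation and the interferon response had 8 female-higher members of 26 and Mx2 male-higher (median -0.29, with 5 random lists at or below), among them Oas1a (4.22-fold), Gbp3 (2.86-fold), Oas2 (2.31-fold) and Ifit3 (2.12-fold) in the authors' deposited table. Ribosomal protein genes had a median of -0.21, below all 10000 random lists, with 6 of 72 female-higher and Rps4y2, Rpl26 and Rpl6 male-higher. Female-higher members were Rpl28 (4.93-fold), Rpl21 (3.77-fold) and Rpl36 (3.63-fold, adjusted p = 0.0498) in the authors' deposited table, on 12, 11 and 4 implied reads in male liver (1.13-fold to 14-fold by counting for Rpl36). Rpl29 (at least 3.06-fold, as low as 2.12-fold by counting), Rps18 and Rps19 were also female-higher, and ribosomal protein genes share sequence with many pseudogenes. Of 86 genes of the respiratory chain list, Atp5sl, which encodes no subunit of the chain (1.53-fold), and Ndufv3 (1.34-fold) were higher in male liver in the authors' deposited table. Atp5h (1.46-fold) was higher in female liver in the authors' deposited table, and the median of -0.00 lay inside the random range.

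Circadian clock genes were called in both directions. Of 18 compared genes, Bhlhe41 (14.25-fold), Dbp (5.49-fold), Usp2 (2.17-fold), Per3, Nr1d1, Nr1d2 and Per2 were higher in male liver, and Npas2 (2.67-fold), Cry1, Arntl and Nfil3 in female liver in the authors' deposited table. The list median of 0.25 lay at or above 9991 of 10000 random lists. Among 17 genes of endoplasmic reticulum stress, Asns (2.69-fold), Trib3 (1.67-fold) and Xbp1 (1.33-fold) were higher in male and Ddit3 (1.64-fold) in female liver in the authors' deposited table (median -0.07, inside the random range). Of 16 immediate early and heat shock genes, Egr1 (1.57-fold), Hsp90aa1, Myc, Junb and Hspb1 (at least 5.67-fold) were higher in male and Dusp1 (1.82-fold) and Ier3 (at least 3.31-fold) in female liver, by the authors' deposited table and the floor of 3 reads; the median of 0.05 lay inside the random range.

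Markers of cells other than hepatocytes also differed. Pancreatic acinar genes, digestive enzymes of another organ, were higher in male liver for 8 of 10 compared members, with a median log2 ratio of 3.16 (2.86 with Try5 at its bound of at least 6.11-fold), above all 10000 random lists. Cpb1 was 84.8-fold, Cpa1 31.2-fold and Pnlip 16.1-fold higher in male liver in the authors' deposited table, at a log2 RPKM of 2.12, 1.58 and 2.31 in male liver. Cpb1 had 3 implied reads in female liver, and counting alone allows 19.3-fold to 283-fold. Hepatic stellate cell markers were female-higher for 10 of 17 genes and male-higher for none (median -0.62, below all 10000 random lists), with the collagen genes Col3a1 at 2.73-fold, Col1a1 at 2.56-fold and Col1a2 at 1.93-fold in the authors' deposited table. Kupffer cell and macrophage markers had 9 female-higher genes of 17 (median -0.41, below all 10000 random lists), among them Marco (3.21-fold), Fcgr1 (1.76-fold) and C1qc (1.63-fold), and Cd163 was 1.77-fold higher in male liver in the authors' deposited table. Sinusoidal endothelial markers had a median of -0.22, with 31 random lists at or below, inside the range of lists not matched on level, and Pecam1 alone of 16 was called (1.49-fold higher in female liver in the authors' deposited table).

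The medians of 5 further cell type lists lay inside the random range. Cholangiocyte markers had a median of -0.18, with Sox9 1.92-fold higher in female and Spp1 1.73-fold higher in male liver in the authors' deposited table. T and NK cell markers had a median of -0.53, with Nkg7 at least 4.84-fold higher in female and Cd4 3.20-fold higher in male liver, and B cell markers one of -0.39, with Cd22 7.11-fold (3 implied reads in male liver, 2.20-fold to 36.6-fold by counting) and 2010001M09Rik at least 2.55-fold higher in female liver, by the authors' deposited table and the floor of 3 reads. Counting alone allows folds as low as 3.56 for Nkg7 and 1.71 for 2010001M09Rik. Against random lists not matched on level, the T and NK and the B cell median lay outside. Neutrophil markers had a median of 0.23, with Lcn2 alone called of 8 compared genes, while S100a9 and S100a8 had ratios of 1.80-fold and 1.66-fold toward female liver in the authors' deposited table (adjusted p = 0.184 and 0.403). Erythroid markers had a median of 0.13; Alas2, the erythroid heme synthesis gene, was 6.67-fold higher in male liver, and Hbb-b1 and Hbb-b2 had adjusted p-values of 0.281 and 0.852 in the authors' deposited table. Of lists with fewer than 5 compared members, the adipocyte list had Fabp4 called (2.45-fold higher in female liver) and Car3 and Pparg not (adjusted p = 0.056 and 0.817), the skeletal muscle list Mylpf (11.4-fold higher in male liver, 9 and 1 implied reads, 1.63-fold to 516-fold by counting), and the non-coding RNA list Xist and 9030619P08Rik (4.67-fold higher in female liver) in the authors' deposited table.

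**Figure D4:**
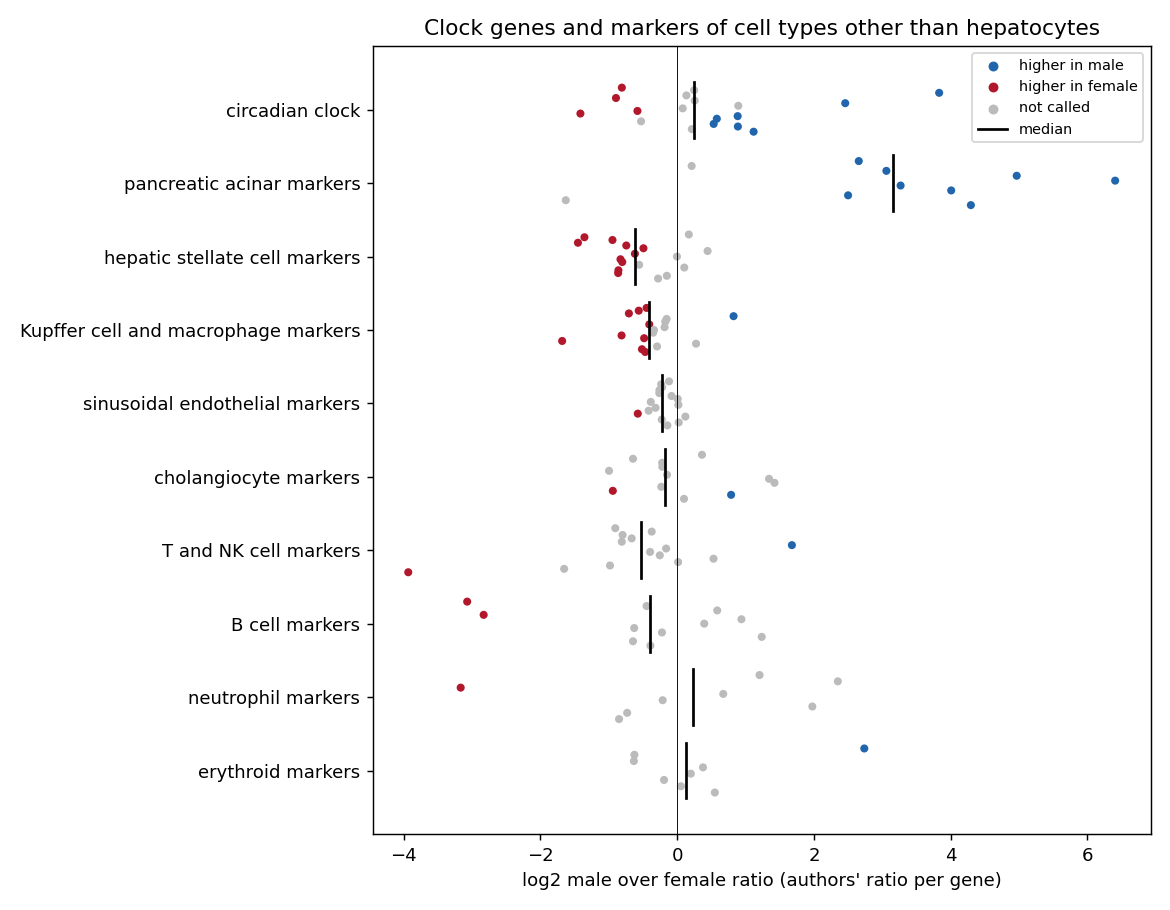
Log2 male over female ratio of each compared gene (1 point per gene, authors' ratio) in the clock list and 9 lists of cell type markers, with the list median as a black bar and colour for the call at an adjusted p under 0.05. Acinar genes lie at a median of 3.16, stellate cell markers at -0.62 and macrophage markers at -0.41.

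Sex-biased genes were spread over the chromosomes with few exceptions. By two-sided Fisher's exact tests of 21 chromosomes in 2 directions, with Benjamini-Hochberg adjustment over all 42 tests, 3 passed an adjusted p of 0.05. All 4 compared genes of the Y, which females lack, were male-higher (adjusted p = 0.00113), an outcome fixed in advance. Chromosome 6 held 74 male-higher genes among 712 compared, 10.4% against 7.03% elsewhere (Fisher's exact test, odds ratio 1.53, p = 0.00132, adjusted p = 0.0205), and chromosome 11 held 56 among 1134, 4.94% against 7.41% (odds ratio 0.649, p = 0.00146, adjusted p = 0.0205). Of the compared X-linked genes, 54 of 431 were female-higher, 12.5% against 10.1% elsewhere (Fisher's exact test, odds ratio 1.27, p = 0.124, adjusted p = 0.462), which did not pass. With a 2-fold minimum, chromosome 11 no longer passed and chromosome 4 did (odds ratio 1.72, adjusted p = 0.041), and among genes with a log2 RPKM of at least 1 in a sex chromosome 6 did not pass.

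Neighbouring genes were called in the same direction more often than by chance. There were 392 adjacent pairs of compared genes called the same way, against a mean of 214.7 and a highest value of 277 over 10000 random placements of the calls (one-sided permutation p = 0.0001, the smallest that 10000 placements can give). Without pairs whose symbols share a stem, an alternative added after the data were seen, 293 pairs remained against a mean of 202.7 (permutation p = 0.0001). Of 294 runs of at least 2 such genes, 19 held at least 4, and the longest held 7. Chromosome 4 held 2 male-higher runs of 7 genes, Mup4, Mup6, Mup7, Mup9, Mup1, Mup12 and Mup13 (59969677 to 60889318, mm9), and Mup17, Mup18, Mup5, Mup20, Mup3, Mup21 and Zfp37 (61252963 to 61869480, mm9). In the first of these the ratios of the members with reads in both sexes reached from 4.96-fold for Mup1 to 140-fold for Mup7, and in the other from 1.59-fold for Mup18 to 136-fold for Mup20, in the authors' deposited table. A female-higher run on chromosome 7 (26682683 to 27724405, mm9) held Cyp2b10 (3.25-fold), Cyp2b13 (60.15-fold), Cyp2b9, Cyp2a4, Cyp2g1 (7.72-fold), Cyp2a5 (1.56-fold) and Cyp2a22 (15.97-fold), and 1 of 3 runs of 6 genes, on chromosome 19 (39763326 to 40188438, mm9), held Cyp2c68 (1.87-fold), Cyp2c40, Cyp2c69, Cyp2c37 (6.05-fold), Cyp2c54 (1.84-fold) and Cyp2c50 (1.43-fold), in the authors' deposited table. Tandem copies of a gene family share sequence, so part of this count can come from reads shared between copies.

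**Figure D5:**
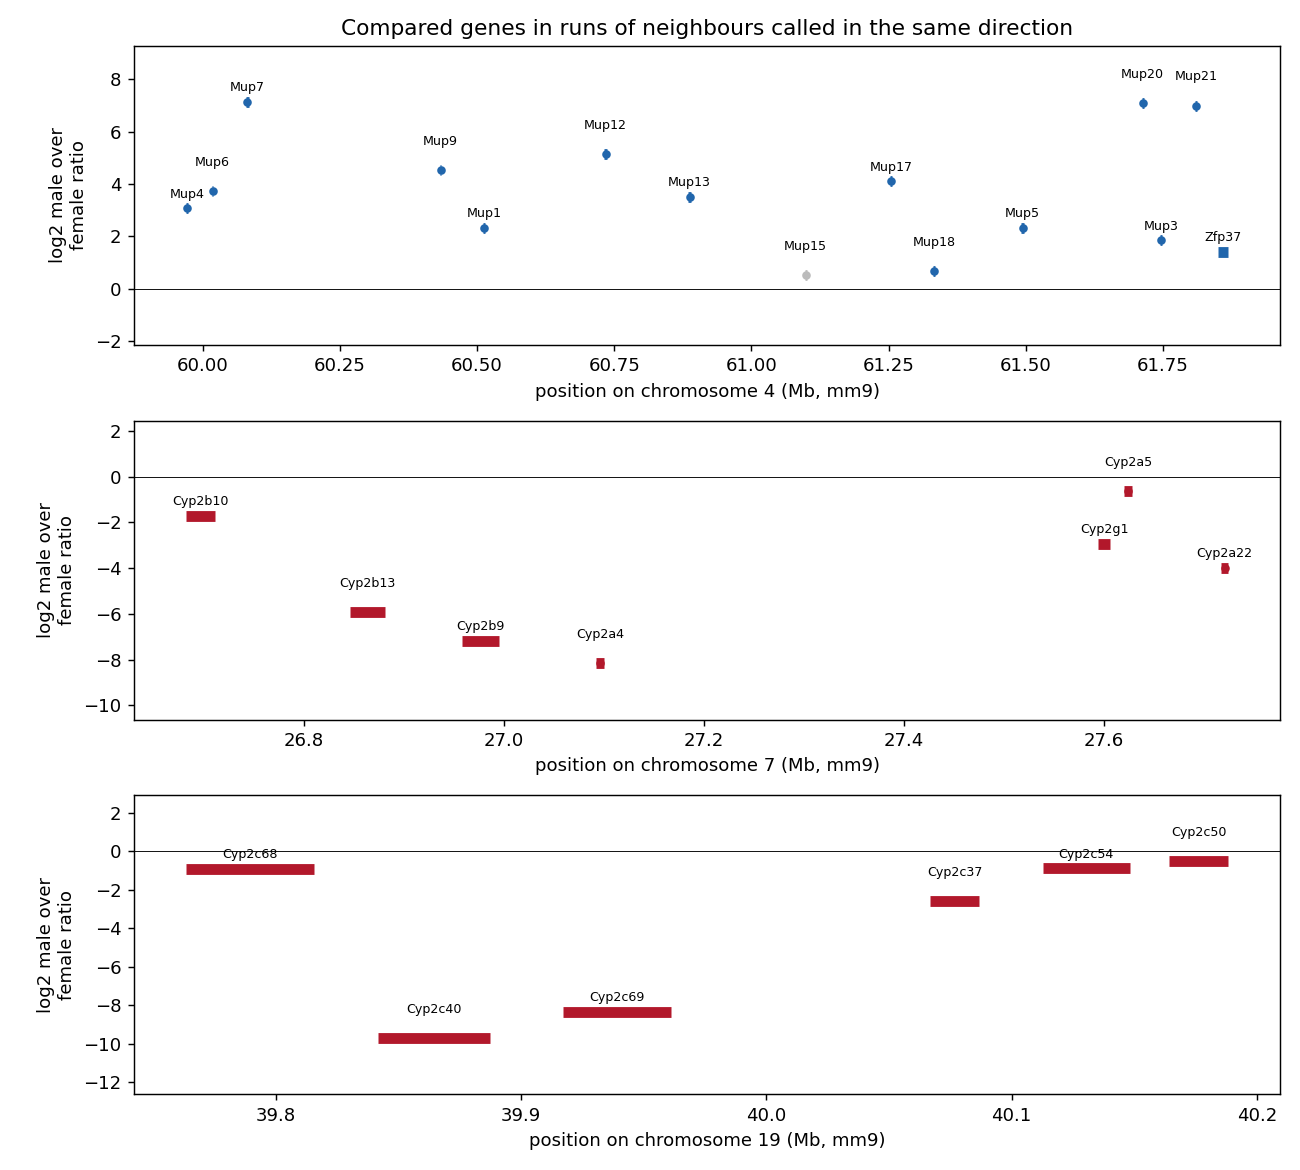
Position of each compared gene (horizontal bars and points, in Mb of mm9) and its log2 male over female ratio by the authors, on chromosomes 4, 7 and 19, over runs of neighbours called in the same direction, of 7 genes each on chromosomes 4 and 7 and, on chromosome 19, 1 of 3 runs of 6 genes. Mup15, in grey, lies between both male-higher runs of 7 genes on chromosome 4 and was not called.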

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

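Of the tests in this part, those on random lists and on the shares of cell types were chosen after the results were seen; those on further acinar genes and on further clock-driven genes were fixed before those genes were looked at.

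Of 1460 genes above the floor in 1 sex alone whose ratio is set to 1, and which enter none of the comparisons, 328 had more than 3 implied reads in 1 sex, the limit that a count of 0 allows, and none in the other, 110 in male and 218 in female liver. The highest number was 9 implied reads and the smallest adjusted p 0.017.

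Pancreatic acinar genes were higher in male liver, with 8 of 10 compared genes called. Of 10000 random lists of the same size and level, 0 held as many male-higher calls (highest 6). The same calls drew attention to the list, and the random lists hold unrelated genes. This count therefore does not decide on scatter of genes with few reads. Pancreas tissue carried into a male pool is a candidate explanation: of 20 further acinar genes, 7 were compared, 5 of them higher in male and none in female liver, with a median log2 ratio of 3.51 (2.5 with 2 genes at their bounds), against a bound of 1 set beforehand, and 5 more had reads in male liver alone. Of the 18 that were found, 6 lay at the floor in both sexes. The most abundant acinar genes other than Cela1, which was present in both sexes (log2 RPKM 5.28 and 4.93), reached a log2 RPKM of 2.31 for Pnlip and 2.30 for Ctrb1 in male liver, while Try4 was not called and lower in male liver. A difference between male and female liver cells stays open as untested, since values per pool were not used here.

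Clock genes were called in both directions, 7 higher in male and 4 in female liver. Of 10000 random lists of the same size and level, 1 held as many called genes. The clock list too was flagged for these calls, and the random lists hold unrelated genes, so scatter of genes with few reads is not decided by this count. A different time of day at collection cannot be told apart from a sex difference: 5 further genes in phase with Dbp had a median log2 ratio of 0.19, between the bounds of 0.3 and 0 set beforehand, and Lonrf3, the single one called, was higher in female liver. The labels give no time of collection, and a sex difference of the clock itself stays open as untested.

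Stellate cell and macrophage markers were higher in female liver, and an effect of normalization between the sexes was not tested, since normalization centres the ratios. A lower share of hepatocytes in the female samples would raise markers of every other cell type alike and lower those of hepatocytes, and the tests do not decide on it. The stellate and endothelial medians, the first pair tested and picked after the medians were seen, differed (permutation p = 0.0094), whereas a test over 6 lists run afterwards (these, macrophage, cholangiocyte, T and NK, and B cell markers) gave a permutation p of 0.097, each median being below 0, unlike those of neutrophil and erythroid markers (0.23 and 0.13), not in that test. Both tests permuted marker genes, not mice or pools. Markers of a cell type can vary together, so neither p-value covers the spread between animals. Hepatocyte markers were higher in female liver, with medians of -0.62 (pericentral, 9 of 15 female-higher) and -0.27 (periportal, 6 of 16), which goes against the share, but a sex difference of these genes within hepatocytes was not separated from it. Both this share and a sex difference in these cells stay open.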

How the results depend on the processing

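The log2 RPKM difference, the minimum of log2 RPKM 1 and the shared stems were chosen after the data were seen. Male-higher and female-higher genes numbered 992 and 1407, and 573 and 833 at an adjusted p under 0.01, 392 and 692 with at least 2-fold, 312 and 521 with both, 184 and 297 with at least 4-fold (authors' ratio), and 868 and 1114 with at least 1 RPKM in a sex. With a log2 RPKM of at least 1 in a sex they numbered 779 and 895. Fewer genes enter each of these by construction. Without leaving out genes at the floor, 9083 in place of 2399 entries passed the adjusted p of 0.05, the added ones being 6604 with the 0.026 given to floor genes and 80 with reads in 1 sex. No called gene changed direction, of 2398, by the log2 RPKM difference. Of 217 named genes, 23 lose their call at an adjusted p under 0.01. Lists outside the random range numbered 30, 26 and 30 over the alternatives run on all 51 lists, and 31 with the minimum, which leaves fewer lists; 20 were outside when lists given by single symbols alone were used. The X odds ratio was 1.24 to 1.65 and passed under none of the alternatives. Same-direction pairs numbered 306 within 100 kb, 289 with the minimum and 293 without shared stems, each with a permutation p of 0.0001; merging overlapping gene models moved nothing, since 0 compared genes overlap on a strand. Other count tests, filters, library size, pseudocount and leave-one-out settings and an estimated correlation were not run, as they need values per library. No paired analysis was possible because the table has 1 value per sex. Depth limits genes with few reads: bounds at 3 reads moved 5 of 51 list medians, by up to 1.68 for sulfotransferases.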

Other observations

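The tests of gene families in this part were all chosen after the data were seen: 425 symbol stems with at least 5 compared members were tested in each direction (one-sided Fisher's exact test, Benjamini-Hochberg over 850 tests), and 15 passed an adjusted p of 0.05. Beside families already described, guanylate-binding proteins, which are induced by interferon, were female-higher for 7 of 11 compared members (adjusted p = 0.00371), namely Gbp1, Gbp3, Gbp4, Gbp5, Gbp7, Gbp9 and Gbp10. Collagens were female-higher for 11 of 34 (adjusted p = 0.0358), including the basement membrane genes Col4a1, Col4a3 and Col4a5 beside the fibrillar Col1a1, Col1a2 and Col3a1. ADAMTS metalloproteases, which process extracellular matrix, and dual-specificity phosphatases were each female-higher for 7 of 16 (adjusted p = 0.0405). Ectonucleotide pyrophosphatases were male-higher for 4 of 6, Enpp2, Enpp3, Enpp5 and Enpp6 (adjusted p = 0.0358). The collagen and stellate lists share members, so they are not independent of each other.

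For 19 entries the level is missing in both sexes, and 18 of these are marked as liver-expressed in the authors' deposited table; 1 of them passed the adjusted p of 0.05. The adjusted p of 0.026 given to all 6604 entries at the floor or without a level is also carried by 15 genes with reads.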
